A study of Mus musculus with 11 samples.

How the data were processed

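The data were 11 RNA-seq libraries from epithelial cells of the mouse small intestine, 3 from the Control group, 4 from the NFF group and 4 from the SFB group. Per the labels' protocols, live cells were sorted by flow cytometry for EpCAM and against CD45, CD31 and CD44, and total RNA was purified from a frozen lysate. Full-length cDNA was made with the SMART-seq v4 kit (Takara), which amplifies polyadenylated RNA from its tail, and sequencing libraries were made with the NexteraXT kit (Illumina), which fragments and tags cDNA with a transposase. Neither kit adds molecular identifiers or marks the strand, so amplification copies were not removed by identifier and overlapping or antisense genes could share reads.

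The authors deposited 1 table of RPKM values (reads scaled by the length of the gene model and by the library's total) for 11366 genes, with 3 decimals, per the file headers. Reads were aligned with STAR to the mm10 mouse genome, per the submitters' processing notes. The counting tool, its annotation, the gene lengths, the total used for scaling and the rule by which a gene counted as detected are not given in the sources used here. The table held 5 zeros in 5 genes. If reads had left whole-number steps in the low values, ratios between libraries would repeat over genes. Among genes between 0.03 and 0.4 RPKM, the most repeated ratio exceeded all of 50 jittered draws in 3 of 55 pairs of libraries, where about 1 is expected by chance. This check was chosen after the data were seen, and a narrower range tried on some pairs before it had shown no excess. Reads were not recovered from these values, so the depth of each library was unknown and no counting interval was given. Sums of RPKM were 237248 to 302661 per library. All columns of the table belonged to the 11 libraries. The table's Entrez identifiers were matched to RefSeq genes of GRCm38.p6, where 11360 were found, and 15 symbols that a spreadsheet had turned into dates were restored through them. Coordinates came from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names.

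RPKM is not a count, so no count model was used. Values were analysed as log2(RPKM + 1), a scale that understates the change of genes near or under 1 RPKM, and every log2 fold change is on that scale. Genes with an RPKM of at least 1 in at least 3 libraries were tested, which kept 10482 and left out 884. Analyses were run in R 4.3.3 with limma 3.58.1. A linear model with 1 mean per group was fitted to all 11 libraries, so that the 3 groups shared an estimate of the spread with 8 residual degrees of freedom, followed by eBayes with a mean trend. Called genes had a Benjamini-Hochberg adjusted p under 0.05. The comparisons were NFF against Control, SFB against Control and, as a secondary comparison because both diet and colonization differ, SFB against NFF.

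Gene lists were tested with camera of limma, which asks whether a list ranks apart from the other genes, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 39 lists per comparison. The 43 lists covered pathways, epithelial lineages, positions along the gut and cells that the gate could have let through. They held 964 entries, of which 785 were measured, and 4 lists with fewer than 5 tested genes were not tested. Each list was also run with its correlation estimated from these libraries and with fry, a rotation test of whether the genes of a list move at all. The mean log2 level of each list per library was compared between groups by a two-sided exact permutation test, whose smallest possible p was 0.0286 in each comparison.

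The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named, in NFF against Control and SFB against Control, the 8 largest changes in each direction among called genes with a mean RPKM of at least 3, and the 5 largest in SFB against NFF. Where a direction had fewer than 3 such genes, the 3 of lowest unadjusted p were added as not called. From each list described, the rule took up to 4 called genes with the largest change, or up to 2 of lowest unadjusted p where none was called. It always took Ciita, Cd74, H2-Aa, H2-Ab1, H2-Eb1, H2-DMa, H2-DMb1, Saa1, Reg3b, Reg3g, Nos2, Fut2, Epcam, Cd44, Ptprc and Pecam1. Pecam1 was not analysed here, and the values of some genes that the rule took are not reported here. Which lists the text describes was chosen after their values were seen.

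The alternatives were 2 other pseudocounts, no filter and a stricter filter, median ratio scaling, quantile normalization, eBayes without a trend and with robust estimation, array weights, a fit of only the groups compared, the replicate number as a block, and leaving out each library in turn. A fit without the 3 libraries farthest from their groups, a covariate for dividing cells and a second estimate of the array weights were added after the data were seen.

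The scripts were tested on simulated data made from each gene's mean over all 11 libraries and its spread within groups, for the 10482 genes. In each of 5 sets, 200 genes with a mean over 3 on the log2 scale were changed. The list of proliferation genes was also shifted by 0.5, and noise was drawn independently for each gene. At a log2 change of 1 they recovered 77.4% of the changed genes in NFF against Control, 76.6% in SFB against Control and 78.6% in SFB against NFF. At a log2 change of 2 the shares were 97.2%, 93.4% and 95.4%. False calls made up 5.61%, 5.11% and 6.74% of calls in the 3 comparisons. Many listed genes were correlated across the real libraries, and the number of real changes is unknown, so these shares need not hold there.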

Results

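Gene expression was profiled in small-intestinal epithelial cells from wild-type mice of 3 groups. Control mice received standard chow (n = 3), NFF mice a diet low in fermentable fiber (n = 4), and SFB mice standard chow together with colonization by SFB (n = 4), read here as segmented filamentous bacteria, gut commensals that attach to the ileal epithelium. The sorted cells carried the epithelial adhesion molecule EpCAM and lacked CD45, a leukocyte marker, CD31, an endothelial marker, and CD44, which is enriched on crypt cells. The labels do not say whether libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical.

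Epcam was abundant in all 3 groups, whereas transcripts of CD45 and CD44, both sorted against, were low. Epcam stood at 545 ± 64.0 RPKM in Control (SD, n = 3), 618 ± 25.7 in NFF (SD, n = 4) and 587 ± 79.8 in SFB (SD, n = 4), whereas Ptprc, which encodes CD45, stood at 1.25 ± 0.866, 1.89 ± 0.492 and 0.825 ± 0.478. Cd44 was at 0.742 ± 0.261, 0.537 ± 0.139 and 1.70 ± 0.493 RPKM. The first principal component held 42.3% of the variance and the second 20.3%. The libraries farthest from their group means were SFB 4, SFB 2 and Control 2, with root mean square deviations of 0.43, 0.38 and 0.35 on the log2 scale. SFB 3 had only 29 genes under 0.3 RPKM, against 80 to 496 in the other libraries.

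**Figure D1:**
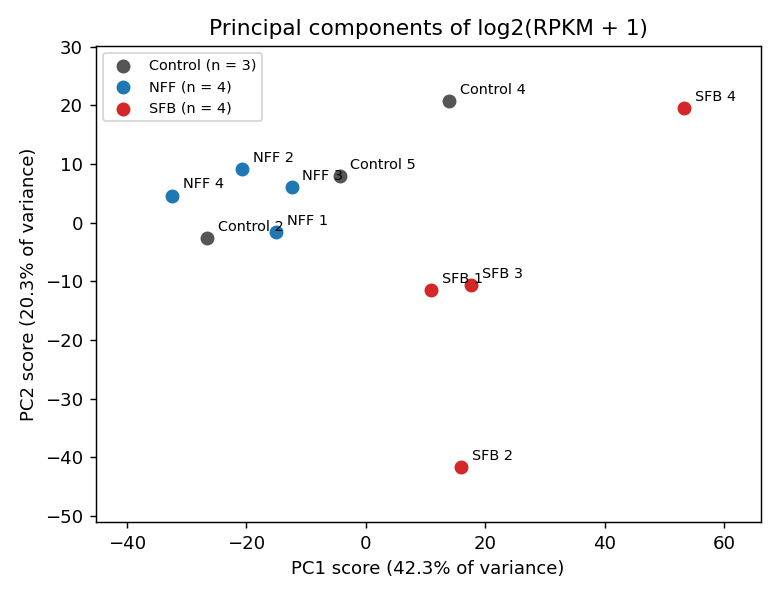
Scores of the 11 libraries on the first and second principal components of log2(RPKM + 1), where each point is a library and colors mark the groups. SFB libraries lie at PC1 scores of 10.9 to 53.2, with SFB 4 at the far end, Control 2 at -26.6 among the NFF libraries and Control 4 at 13.9 within the range of SFB.

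The comparison of NFF with Control bears on how fermentable fiber in the diet relates to antigen presentation by epithelial cells, the subject named in the series title. MHC class II genes, which present antigen to CD4 T cells, did not differ between NFF and Control by more than the spread between libraries. Cd74, the invariant chain, stood at 220 ± 89.7 RPKM in Control (SD, n = 3) and 162 ± 135 in NFF (SD, n = 4), and H2-Ab1, a class II beta chain, at 53.4 ± 16.0 and 43.0 ± 31.9. Ciita, the class II transactivator, stood at 1.23 ± 0.302 and 1.27 ± 0.739 RPKM. The 95% intervals of the log2 difference were -2.09 to 0.54 for Cd74, -1.72 to 0.56 for H2-Ab1 and -0.53 to 0.49 for Ciita, which leave a range of decreases and smaller increases open. Across the 8 tested class II genes the median log2 fold change was -0.54, with 7 values below 0, 0 genes called over all genes and 0 adjusted over the list alone. The list missed the threshold with limma's camera (Benjamini-Hochberg adjusted p = 0.094; adjusted p = 0.705 with an estimated correlation), and the exact permutation test of its mean level gave p = 0.543. Single NFF libraries moved this value, from -0.08 with the test's direction turned and adjusted p = 0.965 without NFF 2, to -1.02 and 5.2e-05 without NFF 3. It was -0.88 without Control 2, where the list stayed uncalled. With the replicate number as a block, a pairing that the labels do not state, the list was called at -0.54 (adjusted p = 0.029).

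No single gene was called between NFF and Control. Limma with Benjamini-Hochberg adjustment gave 0 genes of 10482, with a smallest adjusted p of 0.303, while 505 genes (4.82%) had an unadjusted p under 0.05. Without SFB 4, which enters only the estimate of the spread, 8 genes were called, among them Cyp2u1 (adjusted p = 0.030), Cyp3a11 (0.029), Tmem144 (0.047) and Nqo1 (0.046). The number of genes whose NFF and Control libraries did not overlap was 1024 (9.77%), against 5.71% expected by chance. The genes of lowest unadjusted p with higher values in NFF were Cyp2u1, a cytochrome P450 (log2 fold change 1.11 ± 0.17 SE), Tmem144, a transmembrane protein gene (0.98 ± 0.16), and Gng11, a G protein subunit (0.72 ± 0.15). Those with lower values were Gstm1, a glutathione transferase (-2.24 ± 0.41), Degs1, a ceramide desaturase (-0.74 ± 0.14), and Nqo1, a quinone reductase (-0.76 ± 0.14). Gstm1 stood at 71.8 RPKM in Control 2, at 19.9 and 15.7 in the other Control libraries, and between 4.42 and 6.10 in NFF.

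Lists of genes differed between NFF and Control only where camera used its preset correlation. Chance was not excluded for their number, since 17 of 35 splits of these libraries called at least as many. Camera called 16 of the 39 lists, 6 with higher and 10 with lower values in NFF, but 0 were called with an estimated correlation (smallest adjusted p = 0.617) and 0 by fry. The largest shift toward lower values was in proliferation genes, with 30 of 30 members below 0 and a median of -0.73 (adjusted p = 2.5e-10 by camera; adjusted p = 0.617 with an estimated correlation). Examples were the cyclin Ccnb2 (-1.15) and survivin, Birc5 (-0.97), neither of them called. That median was -0.29 without Control 4 and -1.13 without Control 2, still called in both cases. Genes of oxidative phosphorylation had 40 of 40 members below 0 and a median of -0.22 (adjusted p = 3.8e-09; adjusted p = 0.617 with an estimated correlation), or -0.12 without Control 2. Examples were the ATP synthase gene Atp5g1 (-0.35) and the complex I gene Ndufv2 (-0.28), also not called. No member of either list was called when adjusted over the list alone.

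Interferon gamma response genes had 23 of 27 members below 0 and a median of -0.31 (camera adjusted p = 4.3e-07; adjusted p = 0.617 with an estimated correlation), and 7 members were lower when adjusted over the list alone. The GTPase genes Igtp (-1.34) and Irgm2 (-0.94) led it, neither called over all genes. Their annotated spans overlap on the same strand of chromosome 11, so the authors' counting could have shared reads between them. With the proliferation level as a covariate, a fit chosen after the data were seen, Igtp was called at -1.84 (limma adjusted p = 0.013). MHC class I presentation genes had a median of -0.24 (adjusted p = 2.3e-04; adjusted p = 0.617 with an estimated correlation), led by the immunoproteasome gene Psmb8 (-1.09) and the peptide transporter Tap1 (-0.69), with 3 members lower when adjusted over the list alone. That median was -0.11 without NFF 2, and without Control 2 it was -0.07 and no longer called (adjusted p = 0.167). Genes listed as epithelial responses to SFB and the cytokine IL-22 had a median of -0.35 (adjusted p = 0.123; adjusted p = 0.688 with an estimated correlation), with 2 lower when adjusted over the list alone, among them values of -1.82 for the oxidase maturation factor Duoxa2 and -0.76 for Nfkbiz, an NF-kB regulator. This list was called at -0.61 with the replicate number as a block (adjusted p = 0.0013), without Control 5 (-0.42, adjusted p = 0.037) and without NFF 1 (-0.34, adjusted p = 0.026), and its median was -0.04 without Control 4 and -0.13 without NFF 2, uncalled.

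Xenobiotic metabolism genes had a median of -0.23 (adjusted p = 2.2e-04; adjusted p = 0.617 with an estimated correlation), with 6 members lower when adjusted over the list alone. The cytochrome P450 gene Cyp3a11 stood at 138 ± 69.3 RPKM in Control (SD, n = 3) and 18.7 ± 3.79 in NFF (SD, n = 4), a log2 difference of -2.71 that was not called. The median was -0.15 without NFF 4, and without Control 2 it was -0.10 and no longer called (adjusted p = 0.123).

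Several lists had higher values in NFF. Markers of tuft cells, chemosensory cells of the epithelium, had 18 of 18 members above 0 and a median of 0.38 (adjusted p = 1.2e-04; adjusted p = 0.641 with an estimated correlation), with Gnat3, a taste G protein (1.10), and the kinase Dclk1 (0.64) as examples. The median was 0.24 without NFF 4 and 0.17 without Control 4, where the call was lost (adjusted p = 0.116). Genes of peptide digestion and amino acid transport had a median of 0.32 (adjusted p = 2.2e-04; adjusted p = 0.644 with an estimated correlation), with the peptidase Xpnpep2 at 1.38. Distal small intestine genes had a median of 0.73 (adjusted p = 3.0e-04; adjusted p = 0.617 with an estimated correlation) and bile acid transport genes 0.37 (adjusted p = 0.038; adjusted p = 0.617 with an estimated correlation). Fgf15, the ileal hormone induced by bile acids and a member of both lists, stood at 13.3 ± 14.0 RPKM in Control (SD, n = 3) and 89.1 ± 14.3 in NFF (SD, n = 4), not called, or 2.20 and called without Control 2, SFB 2 and SFB 4 (limma adjusted p = 0.023). Both lists lost their calls without Control 2, at 0.23 (adjusted p = 0.167) and 0.16 (adjusted p = 0.209). The bile acid list also lost its call without NFF 3 (0.36, adjusted p = 0.064) or SFB 3 (0.37, adjusted p = 0.061) and stood at 0.61 without Control 4, and the distal list stood at 0.40 without NFF 4, both still called. Control 2 had a distal list mean of 5.12 on the log2 scale, against 6.75 and 7.0 in the other Control libraries, and a proximal list mean of 5.31, against 3.54 and 3.75. None of the members of the tuft, peptide and bile acid lists was called, whether over all genes or adjusted over the list alone, and 2 distal genes were higher by the latter. With the proliferation level as a covariate, a fit chosen after the data were seen, none of these 4 lists was called, at 0.038 for tuft markers with the direction turned (adjusted p = 0.768), -0.032 for peptide genes (0.284), 0.61 for distal genes (0.078) and 0.42 for bile acid genes (0.811).

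**Figure D2:**
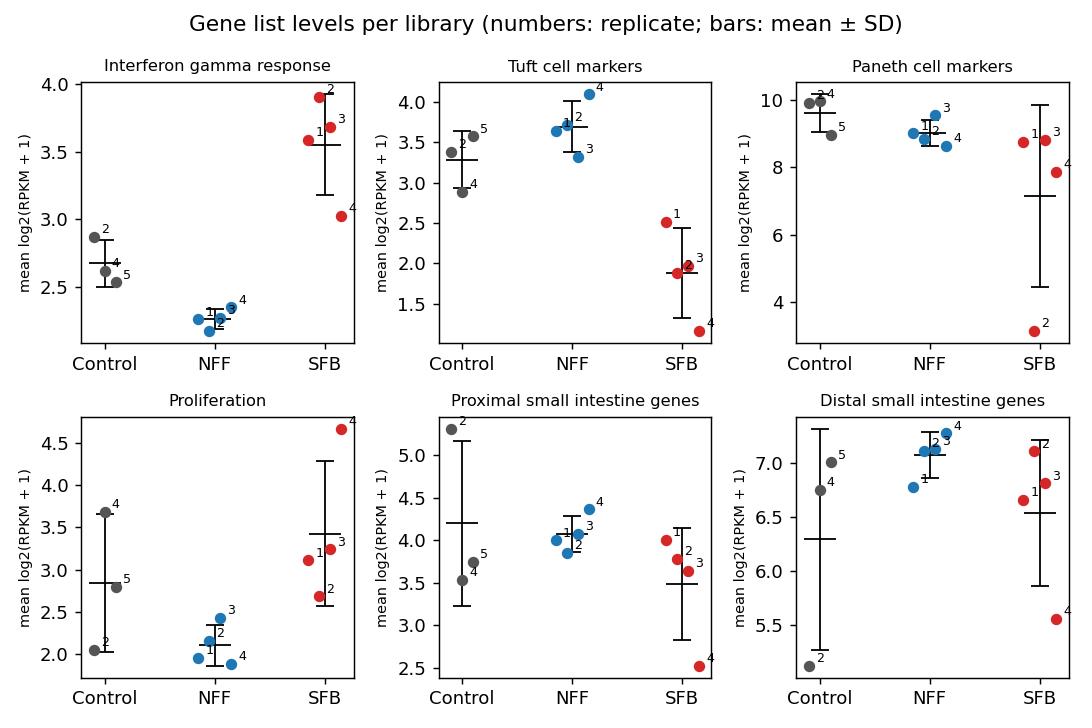
Mean log2(RPKM + 1) of 6 gene lists in each library, with replicate numbers beside the points and the mean ± SD of each group (n = 3 for Control, n = 4 for NFF and SFB). Tuft cell markers lie between 1.16 and 2.52 in SFB against 2.89 to 4.09 in the other libraries, SFB 2 lies at 3.15 for Paneth cell markers, and Control 2 at 5.12 for distal genes.

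The comparison of SFB with Control asks what colonization was accompanied by in mice on the same chow. In SFB 6 of 27 interferon gamma response genes rose, and 2 of 37 xenobiotic genes and 1 of 18 tuft cell markers fell. Limma with Benjamini-Hochberg adjustment called 21 genes of 10482, 13 higher and 8 lower, and 1265 had an unadjusted p under 0.05. Genes whose libraries did not overlap between the groups numbered 1018 (9.71%), against 5.71% by chance. All 21 were also called in the same direction between SFB and NFF. That comparison shares the SFB libraries, so the overlap is not independent, and the overlap expected from sharing was not estimated. Camera called 17 lists, 6 higher and 11 lower, against 0 with an estimated correlation, 3 by fry for a shift in 1 direction and 9 by fry for change in either direction.

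Of the 27 tested interferon gamma response genes, 6 rose, 21 were not called and 20 were higher when adjusted over the list alone. The median was 0.99 (camera adjusted p = 8.9e-19; adjusted p = 0.217 with an estimated correlation; adjusted p = 0.012 by fry). Irgm1, an immunity-related GTPase on chromosome 11 (48861968 to 48871683, GRCm38), rose from 9.96 ± 2.25 RPKM in Control (SD, n = 3) to 24.4 ± 2.48 in SFB (SD, n = 4), a log2 fold change of 1.23 ± 0.14 (SE; limma adjusted p = 0.0044). Irgm2 rose by 1.49 and the T cell-specific GTPase genes Tgtp1 and Tgtp2 by 1.58 and 1.68, though the last are near-identical copies whose reads the authors' counting could have split. Outside the list, the GTPase gene Ifi47 rose by 1.10. Without SFB 2 the calls of Irgm2 (1.33) and Ifi47 (0.97) were lost, as they were without SFB 3 or Control 5. That of Ifi47 was also lost without Control 2, NFF 2 or NFF 3.

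MHC class I presentation genes had a median of 0.32, with 23 of 24 members above 0 (camera adjusted p = 5.3e-09; adjusted p = 0.346 with an estimated correlation). Of them 2 rose and 7 were higher when adjusted over the list alone. Tap1, the peptide transporter subunit on chromosome 17 (34187553 to 34197225), rose from 9.55 ± 0.744 to 25.2 ± 3.45 RPKM (SD, n = 3 and 4), by 1.31 ± 0.16 on the log2 scale (limma adjusted p = 0.0058). Nlrc5, the class I transactivator, rose by 1.20, from 0.834 ± 0.287 to 3.30 ± 1.15 RPKM, a call lost without any library other than SFB 4 (1.06 without SFB 3, limma adjusted p = 0.103).

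MHC class II genes were higher as a list, but no member was called over all genes. The median of the 8 tested genes was 1.33 (camera adjusted p = 3.0e-07; adjusted p = 0.343 with an estimated correlation; adjusted p = 0.093 by fry), and 8 of 8 were higher when adjusted over the list alone. Mean list levels were 4.02 ± 0.46 in Control (SD, n = 3) and 5.37 ± 0.36 in SFB (SD, n = 4), with every SFB library above every Control library. The exact permutation test gave p = 0.0286, the smallest its 35 splits allow, or 0.279 adjusted over the 39 lists. Cd74 stood at 542 ± 131 RPKM in SFB against 220 ± 89.7 in Control, a log2 difference of 1.36 with a 95% interval of 0.05 to 2.68 (limma adjusted p = 0.395). H2-Aa differed by 2.01 (adjusted p = 0.263) and Ciita by 1.21 (adjusted p = 0.057). Ciita was called without NFF 3 (adjusted p = 0.046) or SFB 4 (1.33, adjusted p = 0.031), and H2-DMb2 without SFB 4 (1.16, adjusted p = 0.035) or without SFB 4, SFB 2 and Control 2 (1.38, adjusted p = 0.041). With the proliferation level as a covariate both were called (adjusted p = 0.035 and 0.045).

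**Figure D3:**
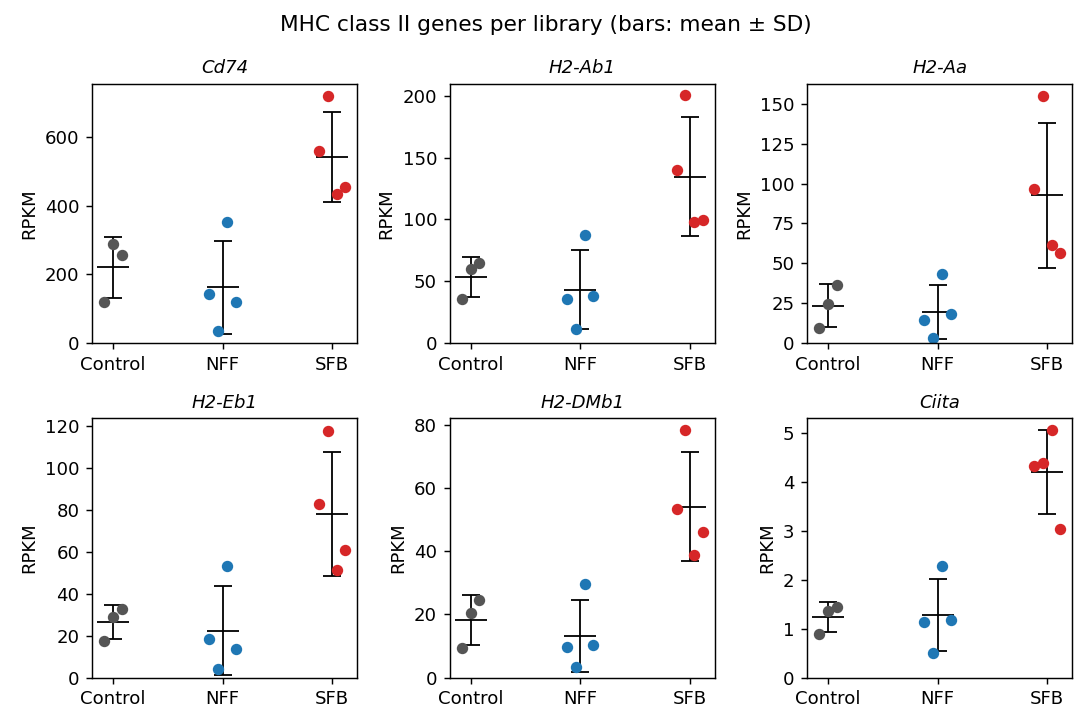
RPKM of 6 MHC class II genes per library, with points for libraries and bars for the mean ± SD of each group (n = 3 for Control, n = 4 for NFF and SFB). Cd74 lies between 435 and 721 RPKM in the SFB libraries and between 33.8 and 352 in the Control and NFF libraries.

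Genes listed as responses to SFB and IL-22 had a median of 0.67 (camera adjusted p = 2.5e-05; adjusted p = 0.310 with an estimated correlation). None was called over all genes, and 11 were higher and 2 lower when adjusted over the list alone. Nos2, the inducible nitric oxide synthase, stood at 30.3 ± 15.1 RPKM in Control and 82.5 ± 30.4 in SFB, the lectin genes Reg3b and Reg3g differed by 1.00 and 1.10, the acute phase gene Saa1 by 3.04 and the fucosyltransferase gene Fut2 by 0.49, none of them called. Saa1 was called without Control 4 (4.18, adjusted p = 0.045), and Nos2 with gene-by-gene array weights (1.26, limma adjusted p = 0.027). Reg3a, a related lectin, differed the other way (-0.98, limma adjusted p = 0.057). It was called without a trend (adjusted p = 0.048), with the proliferation level as a covariate (-0.81, adjusted p = 0.018) and with gene-by-gene array weights (-0.98, adjusted p = 0.0044). Those weights were 5.28 for SFB 1 and 0.18 to 0.84 for the other SFB libraries.

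Tuft cell markers were lower in SFB, with 18 of 18 members below 0 and a median of -1.35 (camera adjusted p = 1.0e-20; adjusted p = 0.219 with an estimated correlation; adjusted p = 0.031 by fry). Over all genes 1 of the 18 fell, and 16 were lower when adjusted over the list alone. The one that fell was Cd24a, a surface glycoprotein also made by Paneth cells, at 145 ± 9.0 RPKM in Control (SD, n = 3) and 47.9 ± 19.3 in SFB (SD, n = 4), a call lost without SFB 2 (-1.48), SFB 3 (-1.66), Control 2 (-1.63), Control 5 (-1.62) or NFF 2 (-1.65). Other secretory lineages had medians of -2.64 for Paneth cells (camera adjusted p = 4.5e-10; adjusted p = 0.473 with an estimated correlation), -0.90 for goblet cells (7.1e-09; adjusted p = 0.473 with an estimated correlation) and -1.09 for enteroendocrine cells (5.9e-05; adjusted p = 0.551 with an estimated correlation). None of their members was called over all genes, and 3, 0 and 0 were lower when adjusted over the list alone. Examples were the Paneth gene Pnliprp2 (-3.44, called without SFB 1 at -4.00 with adjusted p = 0.024), the goblet gene Ern2 (-1.20) and the granin gene Chgb (-1.62). The Paneth median was -1.05 without SFB 2, still called, and the enteroendocrine median was -0.36 without Control 2, no longer called (adjusted p = 0.097). It was also uncalled with the proliferation level as a covariate (-0.55, adjusted p = 0.146).

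Xenobiotic metabolism genes had a median of -0.82, with 34 of 37 below 0 (camera adjusted p = 2.4e-19; adjusted p = 0.217 with an estimated correlation; adjusted p = 0.031 by fry). Of these 2 fell and 21 were lower when adjusted over the list alone. Ugt2b5, a glucuronosyltransferase on chromosome 5 (87124960 to 87140318), fell by 1.55 on the log2 scale, from 36.4 ± 4.87 to 11.8 ± 0.616 RPKM (SD, n = 3 and 4; limma adjusted p = 0.0044), and the glutathione transferase gene Gsta4 fell by 2.07. The Gsta4 and Acaa2 calls were lost without Control 2 (-1.64 and -1.01), SFB 2 (-2.14 and -1.16), SFB 3 (-2.03 and -1.11) or Control 5 (-2.22 and -1.32), and without NFF 2 or NFF 3. The Acaa2 call was also lost without Control 4 or NFF 4. In the PPAR alpha and fatty acid oxidation list the thiolase gene Acaa2 fell by 1.19 and was the single member called, and the list median was -0.21 (camera adjusted p = 4.2e-05; adjusted p = 0.343 with an estimated correlation) with 1 member lower when adjusted over the list alone. Retinoid genes had a median of -0.37 (camera adjusted p = 3.4e-04; adjusted p = 0.447 with an estimated correlation), 0 called and 6 lower when adjusted over the list alone, led by the alcohol dehydrogenase gene Adh1 (-2.85, called without SFB 1 at -3.22 with adjusted p = 0.037) and Rdh16f2 (-1.25, called without Control 4 at -1.59 with adjusted p = 0.045). The retinoid list lost its call without Control 2 (-0.14, adjusted p = 0.091) or SFB 4 (-0.25, adjusted p = 0.090), and with the proliferation covariate (-0.18, adjusted p = 0.10). Without Control 2, SFB 2 and SFB 4 together its median was -0.0013, uncalled (camera adjusted p = 0.710).

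Among the largest changes outside these lists, Plet1, a surface protein of progenitor cells, rose by 2.73 and Jdp2, an AP-1 family repressor, by 1.60. The esterase gene Aadac fell by 2.63, the secretoglobin gene Scgb2b17 by 2.18, the calcium-binding protein gene Rgn by 1.73 and the ficolin gene Fcna by 1.54. Without SFB 3 the values of Plet1, Jdp2, Aadac, Scgb2b17 and Fcna were 2.53, 1.62, -2.34, -2.12 and -1.58, none of them called. Proliferation genes had 30 of 30 members above 0 and a median of 0.61 (camera adjusted p = 3.0e-05; adjusted p = 0.661 with an estimated correlation), with 0 called over all genes or adjusted over the list alone, and Bub1b at 0.87. That median was 1.04 without Control 4, 0.20 without Control 2 and 0.18 without SFB 4, where the call was lost in the last cases (adjusted p = 0.091 and 0.098). Without Control 2, SFB 2 and SFB 4 together it was -0.039 with the direction turned, uncalled (camera adjusted p = 0.880). Myeloid and dendritic cell markers had a median of 0.22 and a mean of -0.08, with camera pointing up and fry down (adjusted p = 0.994; adjusted p = 0.998 with an estimated correlation), 0 called over all genes, and 1 higher and 2 lower when adjusted over the list alone. Lyz2 differed by -1.92 and Itgam by 0.99, neither called. The camera direction of that list turned without Control 2 (0.09), SFB 1 (0.18) or SFB 2 (0.08).

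The count of called genes in SFB against Control moved with single libraries, to 7 without SFB 2, 8 without SFB 3, 10 without Control 5, 11 without NFF 2, 12 without Control 2, 39 without Control 4, 56 without SFB 1 and 94 without SFB 4. Among the 18 named genes called here, Irgm1, Rgn, Tap1, Tgtp1, Tgtp2 and Ugt2b5 kept their calls whichever library was left out, while the other 12 lost theirs without at least 1 library, 12 without SFB 2, 12 without SFB 3, 10 without Control 2, 10 without Control 5, 9 without NFF 2, 7 without NFF 3, 4 without Control 4, 4 without NFF 1, 3 without NFF 4 and 1 without SFB 1, and none changed sign. Fits of only these groups called 1 gene, the replicate number as a block left 0, and 3 of the 35 splits of these 7 libraries, the real one included, called at least as many as 21.

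Fold changes of the comparisons against Control were nearly uncorrelated across the 10482 genes, which are not independent replicates (Pearson r = -0.023). Unchanged groups with a shared simulated Control were made 100 times by shuffling the within-group deviations of all 11 libraries. They gave 0.530 ± 0.280 (SD), from -0.592 to 1, a range that holds the observed value. The covariance was -0.0024 against a simulated 0.0368, a difference of -0.0392, and 48.6% of genes had the same sign against 69.4%. In 99 of the 100 draws the covariance was at least as large as the observed one. No gene was called in both comparisons, where limma called 0 and 21 at an adjusted p under 0.05. The 3 Control libraries could not be split with 2 in each part.

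**Figure D4:**
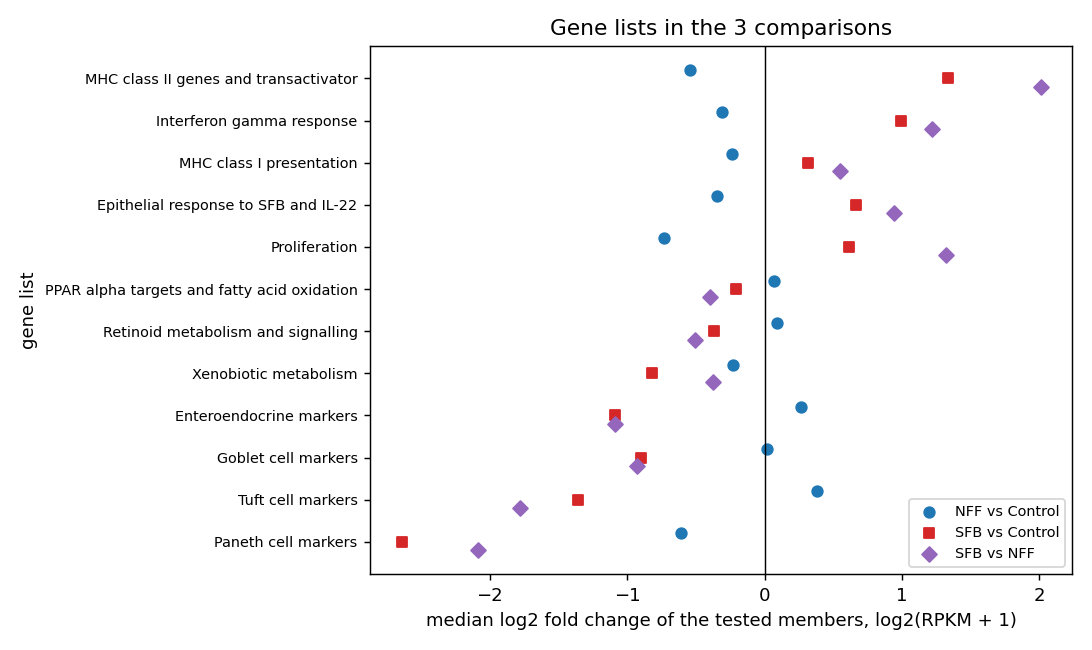
Median log2 fold change of the tested members of 12 gene lists in the 3 comparisons, 1 marker per comparison. MHC class II genes lie at -0.54 in NFF against Control, 1.33 in SFB against Control and 2.01 in SFB against NFF, and tuft cell markers at 0.38, -1.35 and -1.78.

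SFB and NFF differed in both diet and colonization, and they differed most. In SFB relative to NFF, 7 of 8 MHC class II genes, 18 of 27 interferon gamma response genes and 10 of 24 class I presentation genes rose, and 16 of 18 tuft cell markers fell. Limma with Benjamini-Hochberg adjustment called 769 genes, 329 higher and 440 lower in SFB, of which 301 changed by at least 1 on the log2 scale, and 2696 genes had an unadjusted p under 0.05. The libraries of the groups did not overlap in 2101 genes (20.0%), against 2.86% by chance. Camera called 18 lists, 8 higher and 10 lower, against 0 with an estimated correlation (smallest adjusted p = 0.402), 8 by fry for a shift in 1 direction and 27 for change in either direction.

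Of the 8 tested MHC class II genes, 7 rose and 8 were higher when adjusted over the list alone. The median was 2.01 (camera adjusted p = 1.7e-06; adjusted p = 0.402 with an estimated correlation; adjusted p = 0.022 by fry). Ciita, on chromosome 16 (10480059 to 10528418), rose from 1.27 ± 0.739 RPKM in NFF to 4.20 ± 0.851 in SFB (SD, n = 4 each), by 1.23 ± 0.22 on the log2 scale (SE; limma adjusted p = 0.0073). Cd74, on chromosome 18 (60803848 to 60812652), rose from 162 ± 135 to 542 ± 131 RPKM, by 2.14 ± 0.56 (limma adjusted p = 0.040). H2-Aa rose by 2.51, H2-Eb1 by 2.15 and H2-Ab1 by 1.88, which lie together on chromosome 17 between 34257689 and 34316674, and the peptide-loading genes H2-DMb1 and H2-DMa by 2.24 and 1.36. Mean list levels were 3.59 ± 0.96 in NFF and 5.37 ± 0.36 in SFB (SD, n = 4 each), and the exact permutation test gave p = 0.0286, the smallest it allows (0.0796 adjusted over the 39 lists). Ciita alone among these genes kept its call whichever library was left out. Without NFF 2 the others stood at 1.12 (H2-DMa), 1.37 (H2-Ab1), 1.54 (Cd74), 1.60 (H2-Eb1), 1.79 (H2-DMb1) and 1.89 (H2-Aa), none called, and the H2-DMb1 call was also lost without NFF 4 and the remaining calls without NFF 1, NFF 4, SFB 1 or SFB 2 in turn. Without SFB 3 the calls of Cd74, H2-Aa, H2-Ab1 and H2-Eb1 were lost, without Control 5 those of Cd74, H2-Ab1 and H2-Eb1, and without SFB 4 that of Cd74.

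Of the 27 interferon gamma response genes, 18 rose, and 21 were higher and 3 lower when adjusted over the list alone. The median was 1.22 (camera adjusted p = 2.9e-16; adjusted p = 0.402 with an estimated correlation; adjusted p = 5.4e-04 by fry). The ubiquitin-like modifier gene Ubd rose by 4.01, Igtp by 3.25, Irgm2 by 2.42 and Tgtp2 by 2.23, though Igtp and Irgm2 overlap and could share reads. Of the 24 class I presentation genes 10 rose, 14 by adjustment over the list alone, with a median of 0.55 (camera adjusted p = 1.6e-09; adjusted p = 0.402 with an estimated correlation). Tap1 rose by 2.00, the immunoproteasome genes Psmb8 and Psmb9 by 1.92 and 1.71, and H2-Q6, which shares sequence with other H2-Q genes, by 1.75. In the list of responses to SFB and IL-22, 8 of 19 rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.94 (camera adjusted p = 5.6e-05; adjusted p = 0.402 with an estimated correlation). The dual oxidase genes Duox2 and Duoxa2 rose by 2.27 and 3.45, and Reg3g rose by 1.5, though not without NFF 2 (1.36, limma adjusted p = 0.072) or NFF 4 (1.39, adjusted p = 0.064). Saa1 (1.61), Reg3b (1.06), Nos2 (0.84) and Fut2 (0.50) were not called, and this changed for some in other fits. Reg3b was called with quantile normalization (adjusted p = 0.012), eBayes without a trend (0.042) or robust eBayes (0.044), and Nos2 without SFB 4, SFB 2 and Control 2 (0.037). The secreted glycoprotein gene Lrg1 rose by 3.30, with calls lost without NFF 2 (3.28, adjusted p = 0.071), NFF 4 (3.17, 0.074) or SFB 3 (2.91, 0.062), and the antiviral gene Ifitm3 rose by 3.07.

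Of 18 tuft cell markers 16 fell, 17 when adjusted over the list alone, with a median of -1.78 (camera adjusted p = 4.7e-18; adjusted p = 0.402 with an estimated correlation; adjusted p = 0.0056 by fry). Trpm5, the taste-signalling channel on chromosome 7 (143069153 to 143094642), fell by 2.67, from 20.7 ± 4.52 to 2.70 ± 1.87 RPKM (SD, n = 4 each; limma adjusted p = 0.0022). Rgs13, a regulator of G protein signalling, fell by 2.67 and the actin regulator Avil by 2.49. Every NFF library lay above every SFB library in the mean tuft level, from 3.32 to 4.09 against 1.16 to 2.52.

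Lower values in SFB were not particular to tuft cells. Paneth, goblet and enteroendocrine markers had medians of -2.09 (camera adjusted p = 9.2e-05; adjusted p = 0.630 with an estimated correlation), -0.93 (1.7e-06; adjusted p = 0.581 with an estimated correlation) and -1.09 (2.4e-04; adjusted p = 0.582 with an estimated correlation). Of their 19, 19 and 17 members 1, 2 and 2 fell, and 1, 10 and 5 were lower when adjusted over the list alone. These were the Paneth gene Pnliprp2 (-2.54), the guanylin gene Guca2a (-1.20) and the chemokine gene Ccl6 (-1.07) of the goblet list, and the granin genes Chgb (-2.09) and Chga (-1.87). Without NFF 2 none was called, at -2.56, -1.18, -0.99, -2.05 and -1.86, and each call was also lost without NFF 4 and other libraries. The Paneth median was -0.56 without SFB 2, still called, and -0.24, uncalled, without SFB 4, SFB 2 and Control 2 (adjusted p = 0.132). With the proliferation level as a covariate the goblet list (-0.64, adjusted p = 0.229) and the enteroendocrine list (-0.15 with the direction turned, adjusted p = 0.613) were uncalled, and the Paneth list stayed called.

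Proliferation genes had 30 of 30 members above 0 and a median of 1.32 (camera adjusted p = 2.6e-12; adjusted p = 0.529 with an estimated correlation). Of these 3 rose and 29 were higher when adjusted over the list alone, and the 3 were Ccnb2 (1.66), Birc5 (1.58) and Rrm1 (1.65), none of which kept its call whichever library was left out, being lost without NFF 1, NFF 4 or NFF 2 (1.73, 1.59 and 1.69). Crypt stem and progenitor markers had a median of 0.53 (camera adjusted p = 0.0047; adjusted p = 0.630 with an estimated correlation), or 0.28 without SFB 4 and -0.11, uncalled, with the proliferation level as a covariate (adjusted p = 0.985), and 3 rose and 1 fell (3 and 1 adjusted over the list alone). The crypt gene Olfm4 rose by 3.00, Clca3b by 2.24 and Cd44 by 0.80, while the transcription factor gene Sox9 fell by 0.74. Without NFF 2 the calls of Clca3b (2.19) and Sox9 (-0.72) were lost, as they were without NFF 4 (1.96 and -0.72). The proliferation level was highest in SFB 4, at 4.66 on the log2 scale against 2.69 to 3.24 in the other SFB libraries.

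Among absorptive genes, 5 of 20 in the list of brush border carbohydrate digestion and sugar transport fell and 1 rose (11 and 1 adjusted over the list alone), with a median of -0.82 (camera adjusted p = 2.3e-06; adjusted p = 0.478 with an estimated correlation). The gluconeogenic gene Fbp1 fell by 1.61, the sucrase-isomaltase gene Sis by 1.27, the sugar-sensing factor Mlxipl by 1.12 and the maltase gene Mgam by 0.88. Of 20 retinoid genes 6 fell, 7 adjusted over the list alone, with a median of -0.51 (camera adjusted p = 1.8e-04; adjusted p = 0.448 with an estimated correlation), or -0.27 without SFB 4. The retinol dehydrogenase genes Rdh7 and Rdh16f2, close paralogs, fell by 3.33 and 2.12, Adh1 by 2.56 and the retinal dehydrogenase gene Aldh1a1 by 1.64. In the PPAR alpha list 5 of 29 fell and 1 rose (11 and 1 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 2.1e-05; adjusted p = 0.402 with an estimated correlation). The thiolase gene Acaa2 fell by 1.24 and Ppara itself by 0.60, while the ketone body dehydrogenase gene Bdh1 rose by 0.66. Of 37 xenobiotic genes 10 fell, 15 adjusted over the list alone, with a median of -0.38 (camera adjusted p = 2.1e-05; adjusted p = 0.529 with an estimated correlation), or -0.13 without SFB 4. Cyp2d26 and Gsta4 fell by 2.76 and 1.68, and Gstt1 and Ugt2b5 by 1.44 and 1.10. The antitrypsin genes Serpina1e and Serpina1c fell by 3.08 and 2.99, but belong to a family of near-identical copies. Without NFF 2 the calls of Sis (-1.28), Mgam (-0.86), Adh1 (-2.51), Aldh1a1 (-1.68), Ppara (-0.53), Bdh1 (0.64), Gsta4 (-1.55), Gstt1 (-1.43) and Serpina1c (-2.95) were lost, some of them also without other libraries. With the proliferation level as a covariate, a fit chosen after the data were seen, none of these 4 lists was called, at -0.092 for brush border genes with the direction turned (adjusted p = 0.554), 0.012 for xenobiotic genes (0.434), -0.20 for retinoid genes (0.794) and -0.23 for PPAR alpha genes (0.126).

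Myeloid and dendritic cell markers, tested because such cells carry MHC class II, had 1 of 5 higher and 1 lower in SFB than NFF (2 and 2 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 0.714; adjusted p = 0.823 with an estimated correlation), or 0.15 without SFB 2. The integrin gene Itgam rose by 1.41, from 2.39 ± 0.969 to 8.09 ± 3.17 RPKM (SD, n = 4 each), and the protease inhibitor gene Cst3 fell by 0.47. Both calls depended on single libraries, with Itgam uncalled without NFF 2 (1.44, limma adjusted p = 0.056) or NFF 4 (1.21, adjusted p = 0.059). Cst3 was uncalled without any 1 of 8 libraries, at adjusted p up to 0.119 without NFF 4 (-0.40).

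The count of 769 fell to 240 without NFF 2, 303 without NFF 4, 423 without NFF 3 and 503 without SFB 3, and 1 of 35 splits of these 8 libraries, the real one, reached it. Among 78 named genes called here 35 kept their calls whichever library was left out, and the other 43 lost theirs without NFF 2, 38 of them also without NFF 4, with no change of sign.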

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

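The tests of dividing cells, library scaling, leukocytes, tuft cell number and the position of Control 2 were chosen after the results were seen, whereas the splits of the libraries were fixed before. Values were compared within NFF and SFB (n = 4 each), where a library stood out if its gap to the nearest other took up most of the group's range, and 13 of 298 such tests stood out (8 genes and 5 lists), where chance gives about 1 in 20. Control, with 3 libraries, was not tested.

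Cat was at 88.6 RPKM in NFF 4, against 110 to 111 in the other NFF libraries. Cyp2u1 was at 12.2 in NFF 1, against 17.6 to 18.1. Fcna was at 13.6 in NFF 4, against 5.98 to 6.46. H2-DMb2 was at 2.05 in NFF 3, against 1.30 to 1.39. Irgm1 was at 6.22 in NFF 2, against 7.10 to 7.25. Degs1 was at 7.88 RPKM in SFB 4, against 6.51 to 6.61 in the other SFB libraries. Plet1 was at 3.17 in SFB 1, against 16.0 to 17.6. Rrm1 was at 25.9 in SFB 4, against 6.54 to 8.27. Of the mean log2 list levels in SFB, circadian clock genes were at 2.35 in SFB 4 against 2.73 to 2.77, and pattern recognition and NF-kB genes at 3.62 in SFB 4 against 3.81 to 3.83. Retinoid genes were at 2.37 in SFB 4 against 3.11 to 3.24, NRF2 and glutathione genes at 5.84 in SFB 3 against 6.06 to 6.10, and Paneth cell markers at 3.15 in SFB 2 against 7.87 to 8.82.

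In SFB against NFF, 1 of 35 splits of these libraries, the real one, gave 769 called genes, and the highest other gave 0. This argues against chance for that count but cannot exclude it with so few splits. Mixed splits also carry the difference between the groups into the spread, which lowers their counts. Chance cannot be excluded for the 21 genes of SFB against Control, which 3 of 35 splits reached, with 255 in the highest other, a count that points to a structure of the samples. That split set Control 2 with SFB 1, SFB 2 and SFB 3 against Control 4, Control 5 and SFB 4. Control 4 and SFB 4 deviated from their group means together (correlation 0.668). They also had the highest proliferation levels of all libraries, at 3.69 and 4.66 on the log2 scale. In NFF against Control the real count was 0, which 35 of 35 splits reach by construction (highest other 0), so the splits test nothing there. For called lists chance cannot be excluded either, with 17 of 35 splits as large in NFF against Control (16 real, 22 in the highest other), 23 in SFB against Control (17 and 25) and 16 in SFB against NFF (18 and 27).

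MHC class II genes were higher in SFB than in NFF, with a median log2 difference of 2.01. Library scaling was argued against as the whole cause by a median of 2.06 with quantile normalization (limma camera, Benjamini-Hochberg adjusted p = 1.2e-05). With the proliferation level as a covariate the median was 1.86 (limma camera adjusted p = 2.4e-06), which could not decide on a larger share of dividing cells. Proliferation levels did not overlap between NFF (1.89 to 2.43) and SFB (2.69 to 4.66), so the adjustment rested on the relation within groups. For class II genes that relation had a Pearson r of 0.042 (two-sided exact permutation p = 0.874). These calls rest on the preset correlation, and with an estimated one the list was uncalled (adjusted p = 0.402). Leukocytes carried through the sort stay open, since the highest of 8 leukocyte markers was Itgam at 1.41 and their median was 0.26, with Ptprc at -0.69 (called at -0.70 with quantile normalization, limma adjusted p = 0.043), Lyz2 at -1.50, not called, and Cst3 at -0.47, called lower, and several lie near the floor or have a high baseline in epithelium. Most listed leukocyte markers were absent from the deposited values, whose rule for a detected gene is not given. Those measured were 2 of 29 for T cells and intraepithelial lymphocytes, 3 of 17 for B and plasma cells, and 5 of 20 for myeloid and dendritic cells. A candidate explanation is a response to colonization, with 1.33 in SFB against Control on the same chow (uncalled with an estimated correlation, adjusted p = 0.343), while for diet the list had -0.54 in NFF against Control (adjusted p = 0.094) and a part stays open.

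Tuft cell markers were lower in SFB than in NFF, with a median of -1.78. Library scaling was argued against as the whole cause by a median of -1.74 with quantile normalization (limma camera, Benjamini-Hochberg adjusted p = 1.9e-16). With the proliferation covariate the median was -1.34 (limma camera adjusted p = 1.5e-07), which could not decide on dividing cells. Proliferation levels did not overlap between NFF (1.89 to 2.43) and SFB (2.69 to 4.66), so the adjustment rested on the spread within groups. There SFB 4 was highest in proliferation (4.66) and lowest in tuft markers (1.16). With an estimated correlation the list was uncalled (adjusted p = 0.402). Members with a negative value numbered 18 of 18, which fewer tuft cells or less of their RNA per cell could both give, and bulk RNA cannot tell these apart. Colonization stays open as a cause, with -1.35 in SFB against Control on the same chow, as does a part for diet, with 0.38 in NFF against Control (both uncalled with an estimated correlation, adjusted p = 0.219 and 0.641), and other secretory lineages were lower too.

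Distal small intestine genes were higher in NFF than in Control, with a median of 0.73, a call lost with an estimated correlation (adjusted p = 0.617). Without Control 2 the median was 0.23 and the call was lost (limma camera, Benjamini-Hochberg adjusted p = 0.167), which is consistent with 1 library from another position along the intestine carrying much of the size of the difference. Without Control 2, SFB 2 and SFB 4, which were picked for their distance from their groups, the list stayed called at 0.23. Fgf15 was then called at 2.20 (limma adjusted p = 0.023). The SFB libraries enter only the spread here, and leaving out distant ones narrows it. Whether Control 2 carries all of the difference therefore stays open. Library scaling was argued against by 0.74 with quantile normalization (adjusted p = 0.0010). An effect of diet on distal genes stays open.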

How the results depend on the processing

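The fits without the 3 libraries farthest from their groups (Control 2, SFB 2 and SFB 4), with the proliferation covariate and with gene-by-gene array weights were chosen after the data were seen. Called genes numbered 0, 21 and 769 in NFF against Control, SFB against Control and SFB against NFF, and called lists 16, 17 and 18. Over all alternatives, the values of named genes that kept their direction and side of the threshold numbered 929, 986 and 1777, those that lost a call 0, 136 and 292, those that gained one 22, 37 and 10, and those that turned 19, 3 and 5. For the lists described, leaving out the MHC class II list, these numbers were 228, 277 and 488, then 36, 37 and 31, then 3, 0 and 2, then 3, 9 and 17. The cause was not tested for any change below, except that leaving out libraries or groups changes the number of samples. Sequencing depth was unknown, so its part in the spread was not assessed.

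Leaving out 1 library gave 0 to 8 genes in NFF against Control, 7 to 94 in SFB against Control and 240 to 994 in SFB against NFF, and 11 to 21 lists in SFB against Control. In NFF against Control it gave log2 values of -1.02 (without NFF 3, then called) to -0.079 (without NFF 2) for MHC class II genes, -0.22 to 0.16 for Ciita, -1.03 to 0.12 for H2-Aa, -0.14 to 0.20 for Fut2 and -0.42 to 0.29 for Reg3b. In SFB against Control it gave 0.084 to 0.31 for myeloid markers and -0.43 to 0.017 for Ptprc. In SFB against NFF it gave -0.043 to 0.16 for epithelial signals to intraepithelial lymphocytes, 0.0091 to 0.12 for NRF2 genes, -0.38 (without SFB 3) to -0.12 (without NFF 4, and without SFB 4) for clock genes and -0.015 to 0.095 for pattern recognition genes.

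Without the 3 far libraries, 22 genes were called in NFF against Control and 95 in SFB against Control, with 2 shared. Named genes that gained calls were Cyp3a11, Fgf15, Gstm1 and Tmem144 in the former, H2-DMb2 in the latter and Nos2 in SFB against NFF. Fut2 was at 0.078 in NFF against Control, myeloid markers at -0.12 and proliferation genes at -0.039 in SFB against Control, and NRF2 genes at -0.021 in SFB against NFF. The lists of class I presentation, xenobiotic and oxidative phosphorylation genes lost their calls in NFF against Control, and those of enteroendocrine, retinoid, proliferation and PPAR alpha genes in SFB against Control, as did Paneth markers in SFB against NFF (-0.24). With the proliferation covariate, 16 and 187 genes were called in the comparisons against Control, with 2 shared. Among named genes, Cyp2u1, Cyp3a11, Gstm1 and Igtp gained calls in NFF against Control, and Adh1, Ciita, H2-DMb2, Pnliprp2, Rdh16f2 and Reg3a in SFB against Control. In NFF against Control peptide digestion genes were then at -0.032, tuft cell markers at 0.038 with the test's direction turned, and Reg3b at 0.0041. Both lists lost their calls, as did distal (0.61) and bile acid genes (0.42). In SFB against NFF brush border genes were at -0.092, xenobiotic genes at 0.012, crypt markers at -0.11, clock genes at 0.0043, pattern recognition genes at -0.020 and Epcam at 0.055, and the brush border, xenobiotic, crypt, retinoid (-0.20), PPAR alpha (-0.23), goblet (-0.64) and enteroendocrine (-0.15, turned) lists lost their calls. Costimulatory ligands (0.14, camera adjusted p = 0.0092) and epithelial signals to intraepithelial lymphocytes (0.20, adjusted p = 0.014) gained one.

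The estimate of the default array weights stopped before it converged, with a weight of 22.1 for SFB 1 and 0.152 for SFB 4, and its counts of 40, 1948 and 4720 genes with 7 shared are not relied on. It put the SFB and IL-22 list at 0.040, Reg3b at 0.44, Reg3g at 0.044 and Ptprc at -0.053 in NFF against Control, Fut2 at -0.22 in SFB against Control, and Fut2 at -0.094, Epcam at 0.029 and pattern recognition genes at -0.029 in SFB against NFF. Gene-by-gene weights were 5.28 for SFB 1, against 0.84, 0.49 and 0.18 for SFB 2, SFB 3 and SFB 4, so SFB 1 carried most of the SFB mean. They gave 4, 333 and 3017 genes with 1 shared. Reg3b was at 0.31 in NFF against Control, Fut2 at -0.050 in SFB against Control, and Epcam at 0.017 and pattern recognition genes at -0.011 in SFB against NFF. Named genes that gained calls were Cyp3a11, Nqo1 and Tmem144 in NFF against Control, and Nos2 and Reg3b in SFB against NFF. In SFB against Control they were Cd44, Ciita, H2-DMb2, Mptx1, Nos2, Rdh16f2 and Reg3a. Under these weights calls were lost by tuft markers (0.16, camera adjusted p = 0.053) and bile acid genes (0.31, 0.063) in NFF against Control, by enteroendocrine (-0.46, 0.077), PPAR alpha (-0.12, 0.163) and retinoid genes (-0.14, 0.213) in SFB against Control, and by crypt markers (0.25, 0.087) in SFB against NFF. The default weights ended the calls of the same lists and of oxidative phosphorylation genes in NFF against Control, Paneth markers in both comparisons of SFB and xenobiotic genes in SFB against NFF.

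The replicate block gave 0 genes with limma in SFB against Control and 335 in SFB against NFF, MHC class II genes at -0.54 in NFF against Control, now called (camera, Benjamini-Hochberg adjusted p = 0.029), as was the SFB and IL-22 list at -0.61 (adjusted p = 0.0013), Fut2 at 0.078 there, and myeloid markers at 0.24 in SFB against Control. The labels do not say that the numbers pair the samples, and 2 of 8 same-numbered pairs correlated above 0.1 (-0.301 to 0.668). Of 10 libraries with a partner, 3 correlated best with their own number, so the block was not taken as a pairing.

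With an estimated correlation camera called 0 lists in NFF against Control, 0 in SFB against Control and 0 in SFB against NFF, and MHC class II genes, at 1.33 and 2.01, had a limma Benjamini-Hochberg adjusted p of 0.343 and 0.402. Fry called 0, 3 and 8, with MHC class II genes at 1.33 in SFB against Control (adjusted p = 0.093) and myeloid markers at 0.22 with its direction turned. Myeloid markers were also turned at 0.21 with a pseudocount of 5 and at 0.22 with no filter. The pseudocount of 5 put Ciita at 0.0033 and Fut2 at 0.0081 in NFF against Control, and a filter at 5 RPKM put clock genes at 0.022 in SFB against NFF. Quantile normalization gave 1173 genes in SFB against NFF, Epcam at 0.20 there, where Reg3b was now called (limma adjusted p = 0.012), and Reg3b at 0.12 in NFF against Control. Without a trend or with robust eBayes Reg3b was also called in SFB against NFF (adjusted p = 0.042 and 0.044). Median ratio scaling gave 11 genes in SFB against Control, and fits of only the groups compared gave 1 gene in NFF against Control and 1 in SFB against Control.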

Other observations

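The gene lists below were chosen for description after their values were seen, and the relations within groups were tested after the results were seen. In SFB against NFF, type I and III interferon response genes had a median log2 difference of 0.65 over 28 genes (limma camera, Benjamini-Hochberg adjusted p = 1.3e-06; adjusted p = 0.581 with an estimated correlation). Of these 6 rose and 14 were higher when adjusted over the list alone, led by Ifit1bl1 (2.61), Ifi44 (1.43), the antiviral membrane protein gene Bst2 (1.21) and Mx2 (0.96, with the call lost without NFF 2 (0.86), NFF 3, NFF 4 or SFB 1).

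Circadian clock genes went both ways, with 3 higher and 5 lower in SFB than in NFF, over all genes and adjusted over the list alone (median -0.21, limma camera Benjamini-Hochberg adjusted p = 0.166; adjusted p = 0.630 with an estimated correlation; fry for change in either direction, adjusted p = 3.2e-05). The median was -0.12 without NFF 4, -0.12 without SFB 4 and -0.38 without SFB 3, uncalled in each. The repressor gene Nfil3 rose by 1.67, and Nr1d1 fell by 1.54, Dbp by 1.37 and Bhlhe40 by 1.31, with the Nr1d1 call lost without NFF 2 (-1.52). The time of day of collection is not given in the sources used here. NRF2 and glutathione genes had a median of 0.06 (adjusted p = 0.814; adjusted p = 0.908 with an estimated correlation), with 4 higher and 1 lower (5 and 4 adjusted over the list alone). The glutathione enzyme genes Gpx2 and Gsr rose by 1.15 and 1.14 and Nqo1 by 0.66, and the catalase gene Cat fell by 1.20. The Gsr and Nqo1 calls were lost without NFF 2 (1.07 and 0.65) or NFF 4 (1.06 and 0.62).

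Costimulatory and coinhibitory ligands had a median of -0.00028 and a mean of 0.23, with 4 of 8 values above 0 and 2 of 8 higher (2 adjusted over the list alone; limma camera, Benjamini-Hochberg adjusted p = 0.382; adjusted p = 0.672 with an estimated correlation). These were the PD-L1 gene Cd274 (1.47, or 1.40 and uncalled without NFF 2) and the galectin gene Lgals9 (0.61, or 0.54 and uncalled without NFF 2). With the proliferation level as a covariate the list was called at 0.14 (adjusted p = 0.0092). Epithelial signals to intraepithelial lymphocytes had a median of 0.06 (adjusted p = 0.653; adjusted p = 0.863 with an estimated correlation), with 1 higher and 1 lower (3 and 2 adjusted over the list alone). The chemokine gene Ccl28 rose by 1.29 and the receptor gene Il10rb fell by 0.40, both uncalled without NFF 2 (1.29 and -0.44), and Il10rb also without any of 7 other libraries, and the list was called at 0.20 with that covariate (adjusted p = 0.014). Pattern recognition and NF-kB genes had a median of -0.01 (adjusted p = 0.796; adjusted p = 0.899 with an estimated correlation), with 1 higher and 3 lower (3 and 5 adjusted over the list alone). Tlr2 rose by 1.54, and Naip5, which shares sequence with other Naip genes, fell by 1.03, Nfkb2 by 0.81 and Relb by 0.68, the last 3 uncalled without NFF 2 (-1.0, -0.72 and -0.65).

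One hypothesis was that the class II level of a library follows its interferon gamma response level within groups. Over the 11 libraries, each centred on its group, Pearson r was 0.21 (two-sided exact permutation p = 0.370) and Spearman rho 0.10 (permutation p = 0.786), with r at -0.11 without SFB 4 and SFB 2. A relation with the SFB and IL-22 list gave r of 0.39 (permutation p = 0.293) and rho of 0.32 (permutation p = 0.422), with r at 0.48 without Control 4 and NFF 1. A relation with the proliferation level gave r of 0.042 (permutation p = 0.874) and rho of 0.055 (permutation p = 0.891), with r at 0.29 without SFB 4 and Control 4. Adjusted over these 3 relations, the permutation p-values for r were 0.555, 0.555 and 0.874, and for rho 0.891 in each, so no relation passed and such relations could be neither shown nor excluded with 11 libraries.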
